A study of Homo sapiens with 29 samples.

How the data were processed

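The deposited table gave raw counts per gene for 29 libraries, made with HISAT2 2.0.5 and featureCounts 1.5.0-p3 per the submitters' processing notes. Genome build, removal of mouse reads and strandedness of counting were not given in the sources used here. All 58735 gene identifiers and coordinates equalled those of GENCODE release 29 (GRCh38), which was used for annotation. Libraries were random-primed and directional or non-directional, so counts of genes overlapping on opposite strands are uncertain, as are those of paralogs and near-identical copies. Human and mouse tissue share these tumours, and counts of host-type marker genes were taken as they stood. The labels put libraries in 10 groups by LuCaP model and treatment. They were LuCaP 147 with 4 vehicle, 4 batiraxcept and 1 docetaxel library, LuCaP 147CR with 4, 5 and 2, LuCaP 35 with 4 vehicle, 3 batiraxcept and 1 with both drugs, and LuCaP 35CR with 1 vehicle library. That replicates of a group were separate mice was not stated, so p-values measure only the spread between these samples, which may be technical. The series text also names carboplatin; no carboplatin library is among the 29.

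Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, robust quasi-likelihood F-tests, 1 coefficient per group), with the Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Within-model comparisons used the libraries of that model, the comparison of LuCaP 147CR with LuCaP 147 those of both, and the average and interaction over 3 models all 29. Alternatives were DESeq2 1.42.0 (Wald or likelihood ratio test), limma 3.58.1 voom with library quality weights, DESeq2 size factors in edgeR, no filter, a filter of 5 CPM, protein-coding genes alone, a host-tissue score as a covariate, a replicate block, a joint fit or one restricted to the compared libraries, and leaving out each library in turn. Levels are CPM scaled by TMM within each fit, or over all 29 libraries where no comparison is given, and log2 CPM used a prior count of 2. Where all libraries of a group had no counts, a fold is a lower bound against a floor of 3 counts over the group; floors cover counting error only. Groups of 1 library were compared by values alone: genes with a mean of at least 5 CPM that lay at least 2-fold outside the range of the vehicle libraries, and list medians against 10000 random lists matched on mean expression in 20 bins.

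Gene lists, groups, tests, alternatives and the rule for named genes were fixed before the data were examined. The 41 lists (30 of tumour programmes, 11 of host cell types) held 661 distinct genes, 1 of whose symbols was not matched. Those with at least 4 genes tested were tested with limma camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, on ranks, and with fry. The rule named AXL, TYRO3, MERTK, GAS6 and PROS1 in every comparison; the 10 largest rises and 10 largest falls among called protein-coding genes with at least 1 CPM on average and groups that did not overlap, or 5 each way by p where few or none passed; and members of the lists called. Genes on the Y chromosome were left out of the names. Some genes and 2 lists are not reported here, and the counts of alternatives and of libraries far from the others leave them out. The further alternatives were both chosen after the data were seen. One left out the 6 libraries whose profile resembled the other model, found by average linkage on 1 minus Spearman correlation with a height of 0.15, and the other used the profile family as a covariate. Library totals ran from 4087261 to 34830211 counts, with 16820 to 25119 genes counted per library; 3 counts came to 0.0861 CPM in the deepest library and 0.734 CPM in the shallowest. Counts were simulated from the fitted means and spread of each comparison with 100 genes per fold: edgeR found 69 percent of genes changed 2-fold in LuCaP 147, 3 percent in LuCaP 147CR, 0 percent in LuCaP 35 and 19 percent between LuCaP 147CR and LuCaP 147. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.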

Results

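LuCaP 147, LuCaP 147CR, LuCaP 35 and LuCaP 35CR prostate cancer xenografts were grown in the tibiae of RAG2-deficient mice. The mice received vehicle, batiraxcept (a soluble AXL decoy receptor that binds the ligand GAS6), docetaxel or both drugs, and tumour RNA was sequenced at 30 days. The 29 libraries held 4087261 to 34830211 counts (median 15951305). Transcripts of the neuroendocrine genes CHGA and SYP stayed low, with highest values of 1.73 and 8.62 CPM (counts scaled to library size).

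Among the TAM receptors, AXL itself (ENSG00000167601, chromosome 19:41219203–41261766) was almost absent from the counted transcripts: 67 counts in all, in 13 of 29 libraries, with a highest value of 1.02 CPM. TYRO3 (ENSG00000092445, chromosome 15:41557675–41583586) was the most abundant TAM receptor at a median of 19.7 CPM (8.05–43.0), followed by MERTK at 5.36 CPM (1.38–21.6). GAS6, the ligand that batiraxcept binds, had a median of 0.885 CPM and a range of 0 to 35.8, and PROS1, the other TAM ligand, 1.90 CPM (0.210–8.82). In LuCaP 147, TYRO3 stood at 40.3 ± 1.84 CPM with batiraxcept (mean ± SD, n = 4) and 42.1 ± 4.88 with vehicle (n = 4). Its log2 fold change was −0.06 ± 0.12 (estimate ± SE; edgeR, Benjamini-Hochberg adjusted p = 0.885), and no TAM gene that was tested passed the threshold of 0.05 in edgeR for batiraxcept in LuCaP 147, 147CR or 35.

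**Figure D1:**
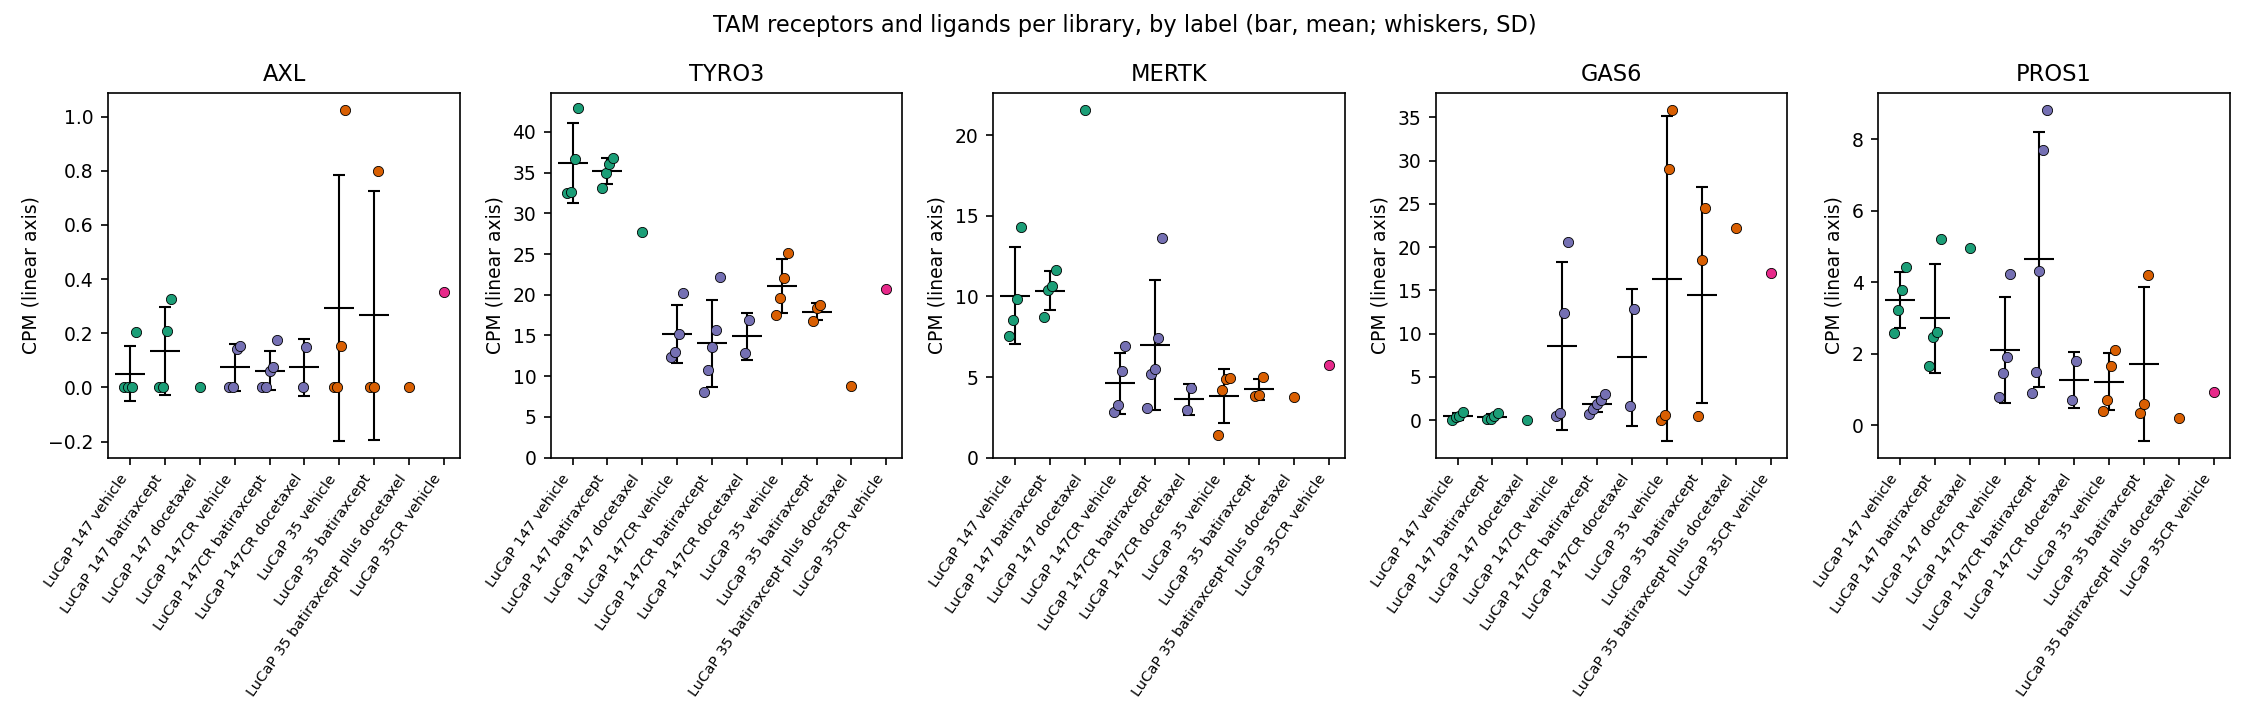
Expression of the TAM receptor genes AXL, TYRO3 and MERTK and of the ligand genes GAS6 and PROS1. Each point is 1 library, in CPM on a linear axis, placed by model and treatment; horizontal bars are group means and whiskers are SDs.

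By overall expression, 6 of the 29 libraries did not resemble their own model. With average linkage on 1 minus Spearman correlation over 13215 protein-coding genes, these 6 parted from the other libraries of the model on their label. The split lay at a height of 0.243, and the next one at 0.129. They were 3 of the LuCaP 147CR libraries (2 of 4 vehicle, 0 of 5 batiraxcept, 1 of 2 docetaxel) and 3 of the LuCaP 35 libraries (2 of 4 vehicle, 1 of 3 batiraxcept). The median correlation of the 3 LuCaP 147CR libraries was 0.961 with the LuCaP 35 libraries that were in place, and 0.767 with those of their own label. The 3 LuCaP 35 libraries had medians of 0.960 with LuCaP 147CR and 0.779 with LuCaP 35. Libraries of LuCaP 147 correlated with each other at a median of 0.977. EPCAM, an epithelial adhesion gene, varied widely between libraries of one label: it had counts in 14 libraries and ranged from 0 to 689 CPM among the 4 LuCaP 147CR vehicle libraries. All comparisons below used the labels as given, and each that involves LuCaP 147CR or LuCaP 35 was repeated without the 6 libraries, an alternative chosen after the data were seen.

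**Figure D2:**
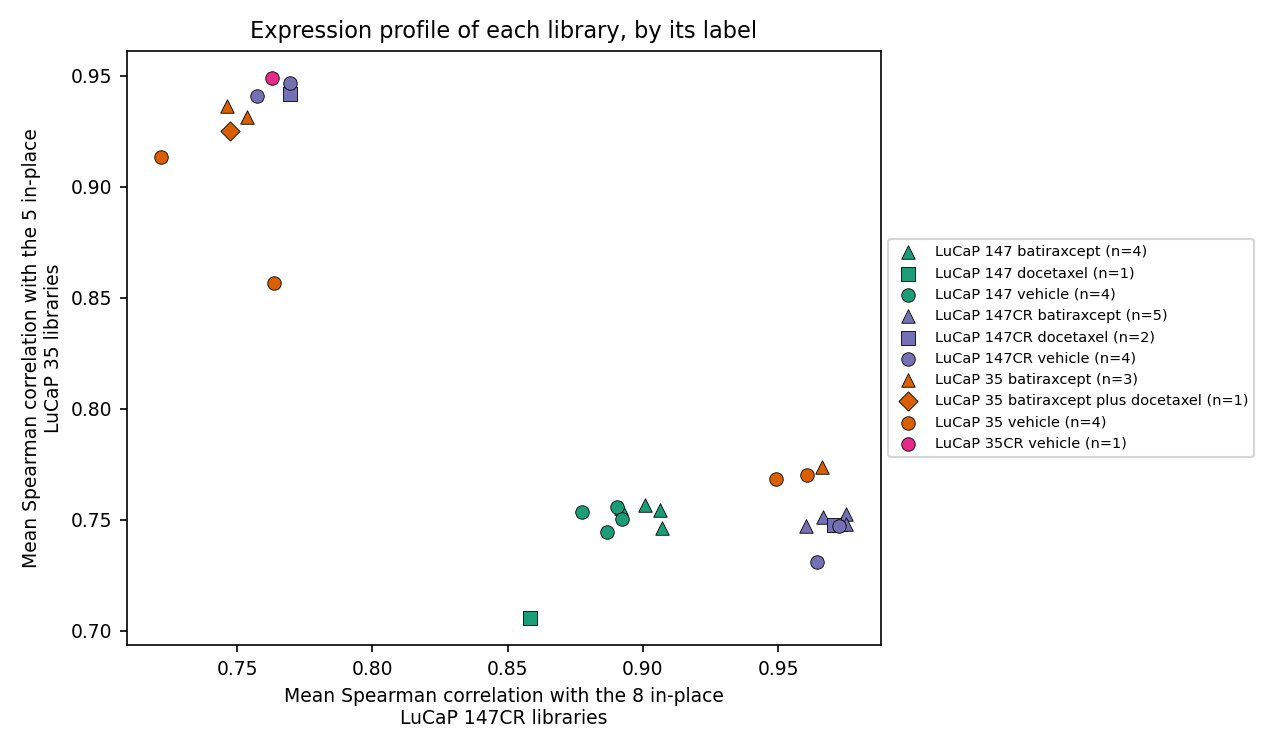
Similarity of each library to LuCaP 147CR and to LuCaP 35. The horizontal axis is the mean Spearman correlation with the 8 LuCaP 147CR libraries in place, the vertical axis that with the 5 LuCaP 35 libraries in place (a library is not compared with itself); colour gives the model on the label and shape the treatment.

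In LuCaP 147 tumours given batiraxcept, transcripts of the mitochondrial genome and of cytosolic ribosomal proteins were lower as groups than in vehicle tumours. All 13 mitochondrially encoded genes had negative log2 fold changes (median −0.68). MT-ND1, a complex I subunit, was at 2640 ± 629 CPM against 4707 ± 1094 (n = 4 and 4, log2 −0.83 ± 0.20), and MT-CO3, a complex IV subunit, had a log2 fold change of −0.67 ± 0.19. Of 28 cytosolic ribosomal protein genes, 27 were negative (median −0.30), RPL38 with 134 ± 14.9 against 195 ± 35.2 CPM (log2 −0.54 ± 0.13). Mitochondrially encoded genes took 8.34 ± 1.85 percent of all counts with batiraxcept and 12.4 ± 2.69 percent with vehicle. Both lists fell by camera with a preset correlation (Benjamini-Hochberg adjusted p = 8.1e-09 for each over 35 lists), and both calls were lost with an estimated correlation (adjusted p = 0.910 with an estimated correlation for each). Adjusted over the list alone, 13 of the 13 mitochondrial genes and 1 ribosomal protein gene fell, against 0 in each list over all genes tested.

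Oxidative phosphorylation genes encoded in the nucleus fell as a list (24 measured, 22 negative, median −0.21, adjusted p = 1.2e-03). MYC and ribosome biogenesis genes fell too (20 measured, 15 negative, median −0.15, adjusted p = 0.031). Of these NOP16, MRTO4 and RRP9 passed over the list alone. The 6 measured androgen-repressed genes were all positive (median 0.64, adjusted p = 0.029). Log2 fold changes were 1.39 for UGT2B15 and 1.58 for UGT2B17, which inactivate androgens by glucuronidation, and 0.76 for FOLH1, which encodes prostate-specific membrane antigen. Each of these 3 camera calls had adjusted p = 0.910 with an estimated correlation, and each was lost without at least 1 of the libraries left out in turn (highest adjusted p = 0.068, 0.184 and 0.263). By single genes, edgeR called 0 of 15830 in the main fit (Benjamini-Hochberg, smallest adjusted p = 0.426), with 1654 at an unadjusted p under 0.05. DESeq2 called 32 (17 higher, 15 lower) and limma voom 0. The uncalled genes named by the fixed rule for their small p included SHROOM3, an actin-binding scaffold (159 ± 11 against 109 ± 13.6 CPM; log2 0.55 ± 0.11), DAPK1, a death-associated kinase (18.2 ± 7.67 against 6.96 ± 1.6; 1.40 ± 0.29), and TNK2, a non-receptor tyrosine kinase (83.8 ± 2.40 against 122 ± 9.40; −0.54 ± 0.10).

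LuCaP 147CR tumours given batiraxcept showed lower hypoxia and glycolysis transcripts and higher p53 response transcripts as groups. Of 22 hypoxia and glycolysis genes, 20 were negative (median −0.59). LDHA, which makes lactate from pyruvate, was at 789 ± 348 CPM against 1818 ± 956 (n = 5 and 4; log2 −1.20 ± 0.51), and PDK1, which restrains pyruvate oxidation, had a log2 fold change of −1.09. Of 18 p53 response genes, 16 were positive (median 0.67). They included CDKN1A, a cell cycle inhibitor (429 ± 205 against 129 ± 82.2 CPM; 1.73 ± 0.54), and BAX, a pro-apoptotic gene (79.1 ± 10.5 against 40.1 ± 12.6; 0.98 ± 0.29). Camera called both (adjusted p = 3.7e-04 and 6.8e-04 over 35 lists). It also called falls in cytosolic ribosomal proteins (median −0.55; adjusted p = 4.5e-06), oxidative phosphorylation (median −0.33; 6.8e-04) and cholesterol synthesis (median −0.43; 5.2e-03). These calls were lost with an estimated correlation (adjusted p = 0.713 with an estimated correlation for each).

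The hypoxia list stayed lower (median −0.87) and the p53 list higher (median 0.38) without the 6 libraries (n = 5 and 2). The mean log2 CPM of the hypoxia list was 6.80 and 7.18 in the 2 vehicle libraries in place. The highest batiraxcept library, at 7.16, lay at that level, and the rest were at 5.20 to 5.76. The docetaxel library in place was at 5.25, so low values were not particular to batiraxcept. The fall in ribosomal proteins was then smaller (median −0.14, adjusted p = 0.030), and the calls for oxidative phosphorylation (−0.17; 0.260) and cholesterol synthesis (−0.20; 0.060) were lost. No list was called with an estimated correlation in this setting (smallest adjusted p = 0.916 with an estimated correlation). BNIP3L, a mitophagy receptor induced by hypoxia, was then at 147 ± 49.1 against 276 ± 46.9 CPM, and BBC3, which encodes the pro-apoptotic PUMA, at 20.9 ± 3.98 against 9.85 ± 4.58. edgeR called 0 of 16221 genes (Benjamini-Hochberg, smallest adjusted p = 0.268; 2638 genes at an unadjusted p under 0.05) and 0 without the 6 libraries (1676 at an unadjusted p under 0.05). DESeq2 called 545 (89 higher, 456 lower) and limma voom 0. PDCD10 (ENSG00000114209, chromosome 3:167683298–167734939), an adaptor of germinal centre kinases, was among the uncalled differences in both settings, at 41.7 ± 2.12 against 87.0 ± 16.2 CPM (log2 −1.06 ± 0.19) and, without the 6 libraries, −0.87 ± 0.15.

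In LuCaP 35 tumours given batiraxcept, interferon-stimulated genes were higher as a group than in vehicle tumours. All 21 measured members were positive (median log2 fold change 2.74), among them the antiviral genes RSAD2 (40.7 ± 33.6 against 2.82 ± 1.73 CPM, n = 3 and 4; log2 3.85 ± 1.16) and CMPK2 (32.2 ± 23.8 against 5.18 ± 1.55; 2.64 ± 0.73). Antigen presentation genes were higher with them (12 of 14 positive, median 1.09), B2M, the light chain of HLA class I, at 949 ± 513 against 399 ± 58.5 CPM. Of the cytosolic ribosomal protein genes, 27 of 28 were negative (median −0.31). Camera called the 3 lists (adjusted p = 1.3e-17, 1.1e-03 and 6.3e-05 over 36 lists), and each call was lost with an estimated correlation (adjusted p = 0.804 with an estimated correlation for each). Leaving out 1 library took the antigen presentation and ribosomal calls to at most 0.226 and 0.275, and kept the interferon call. In the interferon list 0 of 21 members passed in edgeR over all genes tested, and 0 adjusted over the list alone.

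All 22 measured interferon-stimulated genes were positive without the 6 libraries (n = 2 and 2), 16 of them called over the list alone. As a list they were not called with an estimated correlation (adjusted p = 0.684 with an estimated correlation) or by fry (0.222), and the exact permutation p of their mean was 0.333, the smallest possible with these numbers. The vehicle libraries correlated with each other at 0.835, and 1 of them had a mitochondrially encoded share of 17.2 percent, against 5.36 to 5.90 in the other 3 LuCaP 35 vehicle libraries. MX1 (ENSG00000157601, chromosome 21:41420304–41459214), which encodes an antiviral GTPase, was at 130 ± 61.8 against 4.95 ± 1.29 CPM (log2 4.72 ± 0.59), and IFI44L was at least 223-fold higher (17.2 ± 8.76 against 0 CPM; floor of 3 counts over the group). The immediate early list was lower in this setting (median −1.01), with JUN, an AP-1 subunit, at a log2 fold change of −1.80. No list was called here by camera with an estimated correlation (smallest adjusted p = 0.684) or by fry (smallest adjusted p = 0.114). Against the same vehicle libraries, the LuCaP 35CR vehicle library also had a lower immediate early list (median log2 difference −0.935). By single genes, edgeR called 0 of 15809 (Benjamini-Hochberg, smallest adjusted p = 1.00; 68 at an unadjusted p under 0.05) and 0 without the 6 libraries (465 at an unadjusted p under 0.05), DESeq2 0 and limma voom with library weights 3914 (2487 higher, 1427 lower). In simulated counts with the size and spread of this comparison, edgeR found 0 percent of genes set to change 4-fold, against 85 percent in LuCaP 147 and 39 percent in LuCaP 147CR. Simulated without the 6 libraries, edgeR found 74 percent in LuCaP 147CR and 0 percent in LuCaP 35.

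**Figure D3:**
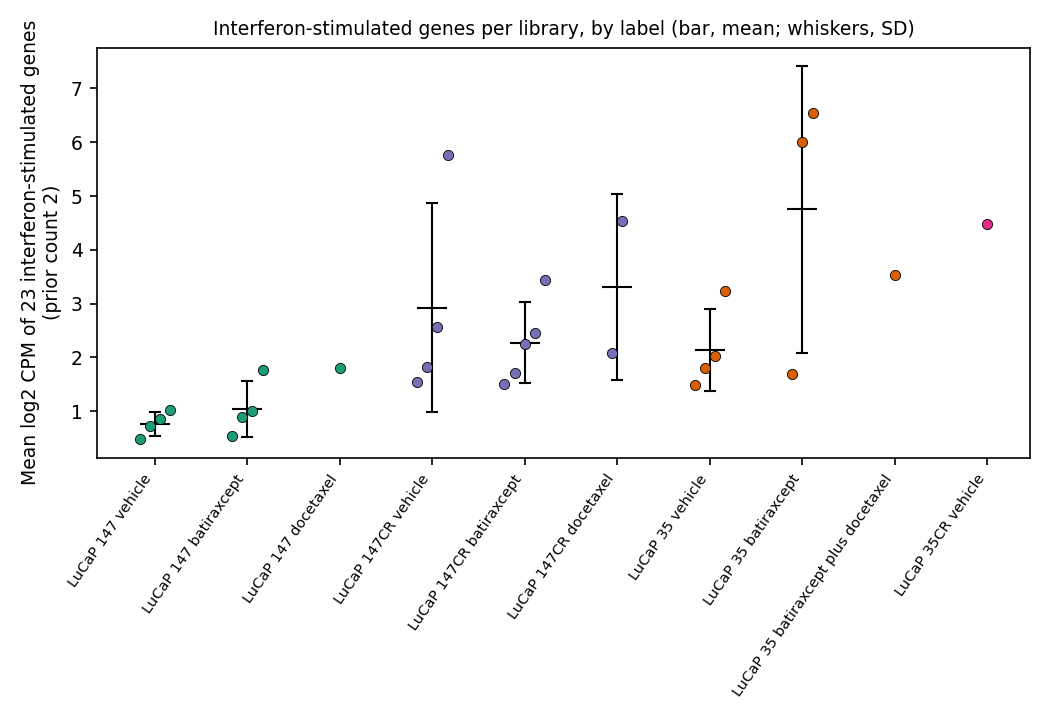
Mean log2 CPM (prior count 2) of 23 interferon-stimulated genes in each library, by model and treatment. Each point is 1 library; horizontal bars are group means and whiskers are SDs. The groups follow the labels as given and include the 6 libraries that resembled the other model.

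Averaged over LuCaP 147, 147CR and 35, batiraxcept tumours had lower ribosomal protein transcripts and higher interferon-stimulated transcripts. All 28 ribosomal protein genes were negative (median −0.37, camera adjusted p = 3.9e-24 over 39 lists, adjusted p = 0.281 with an estimated correlation), with a log2 fold change of −0.37 ± 0.12 for RPS6. In each of the 3 models, other splits of the same libraries gave a smaller camera p for this list than the real groups (below). Such splits were not run for this list on the average. Of 23 interferon-stimulated genes, 18 were positive (median 0.52; adjusted p = 9.3e-07, and adjusted p = 0.640 with an estimated correlation). The mean log2 CPM of the interferon list differed by 2.61 in LuCaP 35, 0.28 in LuCaP 147 and −0.65 in LuCaP 147CR (exact permutation p = 0.171, 0.4 and 0.587; average 0.74, p = 0.243), and the list was not tested for a difference between models. Basal epithelial genes (median 0.27) and p53 response genes (0.17) rose as lists. MYC and ribosome biogenesis (−0.21), hypoxia and glycolysis (−0.16), oxidative phosphorylation (−0.14) and mitochondrially encoded genes (−0.21) fell, with adjusted p from 1.5e-03 to 0.031 over these 6 lists. The smallest estimated-correlation value among them was that of the basal list (adjusted p = 0.355 with an estimated correlation). Leaving out 1 library ended the calls for the mitochondrially encoded (up to 0.94), p53 (0.308), hypoxia (0.067) and oxidative phosphorylation (0.054) lists. edgeR called 0 genes (Benjamini-Hochberg; 894 at an unadjusted p under 0.05), DESeq2 57 (6 higher, 51 lower) and limma voom 0.

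The same average gave 43 genes in edgeR (32 higher, 11 lower) without the 6 libraries. With the profile family as a covariate it gave 0 (edgeR, Benjamini-Hochberg, smallest adjusted p = 0.297). The values that follow are without the 6 libraries. The interferon list was positive in 23 of 23 members (median 1.59), 3 called over all genes tested and 17 over the list alone, while the oxidative phosphorylation list turned direction. LuCaP 35 carried most of the interferon average, with a difference in mean log2 CPM of 3.64 (n = 2 and 2), against 0.28 in LuCaP 147 and 0.59 in LuCaP 147CR. The interferon list was the 1 list called with an estimated correlation (adjusted p = 0.0172 with an estimated correlation; 1.8e-19 with the preset, and from 1.8e-19 to 0.640 over all alternatives of this list). USP18, which removes ISG15 from proteins, rose by a log2 fold change of 0.81 ± 0.14 (edgeR, Benjamini-Hochberg adjusted p = 0.0245) and HERC6, a HECT-domain ubiquitin ligase gene, by 0.82 ± 0.15 (adjusted p = 0.0259). HLA-E, a non-classical HLA class I gene, rose by 0.85 ± 0.12 (edgeR, Benjamini-Hochberg adjusted p = 6.8e-03; 6.8e-03 to 1.00 over all alternatives). PCDH1, a protocadherin, rose by 0.80 ± 0.14 (adjusted p = 0.0192). Its means were 34.3 and 19.9 CPM in LuCaP 147, 82.4 and 62.3 in LuCaP 147CR and 88.1 and 37.8 in LuCaP 35 for batiraxcept and vehicle. Of the endothelial list, VWF rose (1.52 ± 0.29, edgeR adjusted p = 0.0368). This joint fit shared 1 spread over the models (common biological coefficient of variation 0.398). LuCaP 35 fitted alone without the 6 libraries had 0.598, so calls carried by LuCaP 35 may be too many.

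Whether batiraxcept acted differently in the 3 models was tested as an interaction. edgeR called 0 genes with all libraries (Benjamini-Hochberg, smallest adjusted p = 0.271 for PDCD10; 2119 genes at an unadjusted p under 0.05), DESeq2 44 and limma voom 7541. With the profile family as a covariate edgeR also called 0 (smallest adjusted p = 0.685). It called 44 when the 6 libraries were left out, the setting of the values that follow. PLSCR1, an interferon-induced scramblase, was at 28.9 ± 4.22 CPM with batiraxcept and 1.85 ± 1.43 with vehicle in LuCaP 35 (n = 2 and 2), against 15.8 ± 1.81 and 15.3 ± 2.66 in LuCaP 147 (n = 4 and 4) and 19.3 ± 4.51 and 19.1 ± 2.88 in LuCaP 147CR (n = 5 and 2; interaction in edgeR, Benjamini-Hochberg adjusted p = 5.4e-03). STOM, a membrane scaffold gene, went from 0 to 3.84 ± 1.76 CPM in LuCaP 35 (adjusted p = 3.3e-04). The log2 fold change of PDCD10 was 0.97 ± 0.20 in LuCaP 35, −0.86 ± 0.16 in LuCaP 147CR and 0.13 ± 0.14 in LuCaP 147 (edgeR interaction, adjusted p = 8.7e-03). These calls used the spread shared over the models (0.398). In LuCaP 35 fitted alone without the 6 libraries it was 0.598, and edgeR called 0 genes. The shared spread may thus be too small for differences carried by LuCaP 35.

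Docetaxel in LuCaP 147CR (2 libraries, against 4 of vehicle) went with lower androgen-induced and higher immediate early transcripts. KLK2, an androgen-induced kallikrein, was at 5.03 ± 1.91 against 17.9 ± 10.4 CPM (log2 −1.83 ± 0.58), and KLK3, which encodes PSA, had a log2 fold change of −1.62. Camera called the androgen-induced list lower (18 of 24 negative, median −0.27, adjusted p = 1.6e-03 over 37 lists, adjusted p = 0.178 with an estimated correlation). It called the immediate early list higher (15 of 18 positive, median 0.37; 9.6e-03, adjusted p = 0.352 with an estimated correlation). Both calls were lost without at least 1 of the libraries left out in turn (up to 0.549 and 0.426). edgeR called 0 of 18210 genes (Benjamini-Hochberg, 143 at an unadjusted p under 0.05), as did DESeq2 and limma voom. It also called 0 without the 6 libraries (1121 at an unadjusted p under 0.05), where 1 docetaxel library remained. In that setting the androgen-induced list stayed lower (median −0.48, 4 genes over the list alone) and the immediate early list lost its call (0.43; adjusted p = 0.057), in tests that take the lone docetaxel library to vary like the other groups. None of the lists was called with an estimated correlation there (smallest adjusted p = 0.923 with an estimated correlation).

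Set against batiraxcept, docetaxel in LuCaP 147CR (2 and 5 libraries) had higher hypoxia (median 0.80), ribosomal protein (0.55), mitotic (0.35), cholesterol synthesis (0.38) and microtubule (0.46) lists. Also higher were the ATF4 and unfolded protein response (0.34), antigen presentation (0.86), interferon (1.5) and oxidative phosphorylation (0.33) lists. The p53 response (−0.50) and mitochondrially encoded (−0.58) lists were lower. Camera adjusted p ranged from 8.0e-05 to 0.039 for these lists (38 tested), and none was called with an estimated correlation (smallest adjusted p = 0.817 with an estimated correlation). Leaving out 1 library ended or reversed each of these calls in at least 1 case. edgeR called 0 genes (Benjamini-Hochberg, smallest adjusted p = 0.580; 1491 at an unadjusted p under 0.05), DESeq2 4 and limma voom 0. Leaving the 6 libraries out (1 and 5 remained), edgeR called 2, both lower with docetaxel: LBH, a transcription cofactor (20.2 against 107 ± 14.3 CPM; log2 −2.40 ± 0.28), and FAM129A, an ER-stress-induced gene (22.4 against 114 ± 14; −2.34 ± 0.29), each with Benjamini-Hochberg adjusted p = 0.0412. That test takes the lone docetaxel library to vary like the other groups. In this setting the hypoxia, oxidative phosphorylation, ribosomal protein and interferon lists turned direction. The docetaxel library left out, replicate 2, held the higher values. Its mean log2 CPM was 7.77 for the hypoxia list and 4.53 for the interferon list, against 5.25 and 2.08 in the other docetaxel library.

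Between vehicle tumours, the castration-resistant LuCaP 147CR differed broadly from LuCaP 147. Sterol synthesis, androgen-induced and hypoxia genes were higher and p53 and basal genes lower. IDI1, which makes the isoprenoid precursor DMAPP, was at 274 ± 45.8 CPM in LuCaP 147CR and 46.5 ± 5.89 in LuCaP 147 (n = 4 and 4, log2 2.56 ± 0.19, edgeR with Benjamini-Hochberg adjusted p = 4.9e-07). INSIG1 and STARD4, of sterol sensing and transport, rose by 1.94 and 2.74. The androgen-induced STEAP4, a metalloreductase, rose from 35.8 ± 10 to 204 ± 93.9 CPM (log2 2.51 ± 0.42, adjusted p = 3.9e-04). KRT5 (ENSG00000186081, chromosome 12:52514575–52520687), a basal keratin, was at 71.6 ± 8.51 CPM in LuCaP 147 and without a count in LuCaP 147CR, at least 1735-fold lower. edgeR called 4806 of 15714 genes (2736 higher, 2070 lower; Benjamini-Hochberg, threshold 0.05), DESeq2 5755 (3200 higher, 2555 lower) and limma voom 3512. Without the 6 libraries edgeR called 6796 (3410 higher, 3386 lower), of which 3570 were among the 4806 in the same direction.

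Of 20 cholesterol synthesis genes, 14 rose and 0 fell over all genes tested (14 over the list alone, median 1.46). Camera called the list (adjusted p = 9.7e-08 over 34 lists, adjusted p = 0.288 with an estimated correlation), and 13 of its genes rose without the 6 libraries, where IDI1 kept a log2 fold change of 2.40. Fatty acid synthesis followed, with 6 of 12 higher (6 over the list alone, median 1.17, adjusted p = 3.7e-03, adjusted p = 0.287 with an estimated correlation). FASN, the fatty acid synthase, rose from 1290 ± 261 to 3222 ± 544 CPM (1.32 ± 0.28). Androgen-induced genes rose in 12 of 24 and fell in 0 (14 over the list alone, median 1.61, adjusted p = 2.6e-04, adjusted p = 0.109 with an estimated correlation). Among them were HERC3 (2.14) and ACSL3, an acyl-CoA synthetase (2.27). Hypoxia and glycolysis genes rose in 10 of 22 (13 over the list alone, median 1.19, adjusted p = 1.9e-04, adjusted p = 0.640 with an estimated correlation) and in 16 without the 6 libraries. VEGFA, an angiogenic factor, rose by 1.79, and BNIP3L was among them (219 ± 73.6 against 62.6 ± 9.45 CPM, 1.81 ± 0.26). The mean log2 CPM of the hypoxia list was 5.18 to 5.74 in LuCaP 147 vehicle libraries. Among treated LuCaP 147CR libraries in place, docetaxel was at 5.25 and batiraxcept at 5.20 to 5.76, except 1 at 7.16. The rise was thus seen in vehicle libraries and not in most treated ones, and 2 vehicle libraries remained without the 6.

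Of 18 p53 response genes, 8 fell and 2 rose (9 and 2 over the list alone, median −0.83, adjusted p = 6.1e-03, adjusted p = 0.561 with an estimated correlation). BBC3 fell from 94.2 ± 17.5 to 12.0 ± 3.73 CPM (log2 −2.98 ± 0.26; edgeR, Benjamini-Hochberg adjusted p = 2.3e-06) and BAX from 225 ± 25.9 to 42.6 ± 13.6 (−2.40). With the 6 libraries left out these values were −3.25 and −2.06. Basal epithelial genes fell in 3 of 10 (3 over the list alone, adjusted p = 4.5e-03, adjusted p = 0.413 with an estimated correlation): KRT5, KRT17 (at least 561-fold lower) and KRT14 (−3.47). LIF, a cytokine of the interleukin-6 family, fell from 21.2 ± 3.36 to 0.507 ± 0.314 CPM (−5.39 ± 0.55), and INSR, the insulin receptor, rose from 0.372 ± 0.470 to 24.9 ± 4.87 (6.04 ± 0.78).

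Interferon-stimulated genes rose in 13 of 20 (15 over the list alone, adjusted p = 3.7e-03, adjusted p = 0.640 with an estimated correlation). ATF4 and unfolded protein response genes rose in 10 of 20 with 1 lower (11 and 1 over the list alone, median 1.03, adjusted p = 1.4e-03, adjusted p = 0.413 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 10 of 24 with 1 lower (12 and 1 over the list alone, median 0.50, adjusted p = 6.1e-03, up to 0.057 leaving out 1 library, adjusted p = 0.654 with an estimated correlation). Mitochondrially encoded genes fell in 8 of 13 (8 over the list alone, median −1.11, adjusted p = 7.3e-03, adjusted p = 0.654 with an estimated correlation). Camera no longer called these 4 lists, nor the p53 and basal lists, without the 6 libraries. OAS3, which makes the activator of RNase L, had a log2 fold change of 4.81 with all libraries and 1.53 without the 6.

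The genes with the largest rises and falls by the fixed rule were near on-off differences. From no count in LuCaP 147, FAM20C (ENSG00000177706, chromosome 7:192969–260745), a kinase of secreted phosphoproteins, reached 29.1 ± 5.34 CPM in LuCaP 147CR (at least 476-fold higher, and at least 446-fold without the 6 libraries). PANX2, a pannexin channel gene, was at least 364-fold higher, and MCTP2 at least 380-fold. Lower to no count were FAM178B (35.7 ± 7.05 CPM in LuCaP 147; at least 865-fold), MFAP2, a microfibril gene (at least 709-fold), PTGIS, the prostacyclin synthase (at least 357-fold), and ME3, a mitochondrial malic enzyme (at least 242-fold). KRT4 was at 66.5 ± 16.1 CPM in LuCaP 147 and 0.0186 in LuCaP 147CR, and CNN3, a calponin, at 59.8 ± 3.53 and 0.0184. TYRO3 fell from 39.8 ± 4.95 to 16.5 ± 4.53 CPM (log2 −1.27 ± 0.25; edgeR, Benjamini-Hochberg adjusted p = 1.5e-03; −1.56 without the 6 libraries). GAS6 rose by 4.33 ± 1.20 (adjusted p = 0.0116), a call that was lost without the 6 libraries, where its log2 fold change was 0.59 (adjusted p = 0.661; 3.3e-04 to 0.661 over all alternatives).

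**Figure D4:**
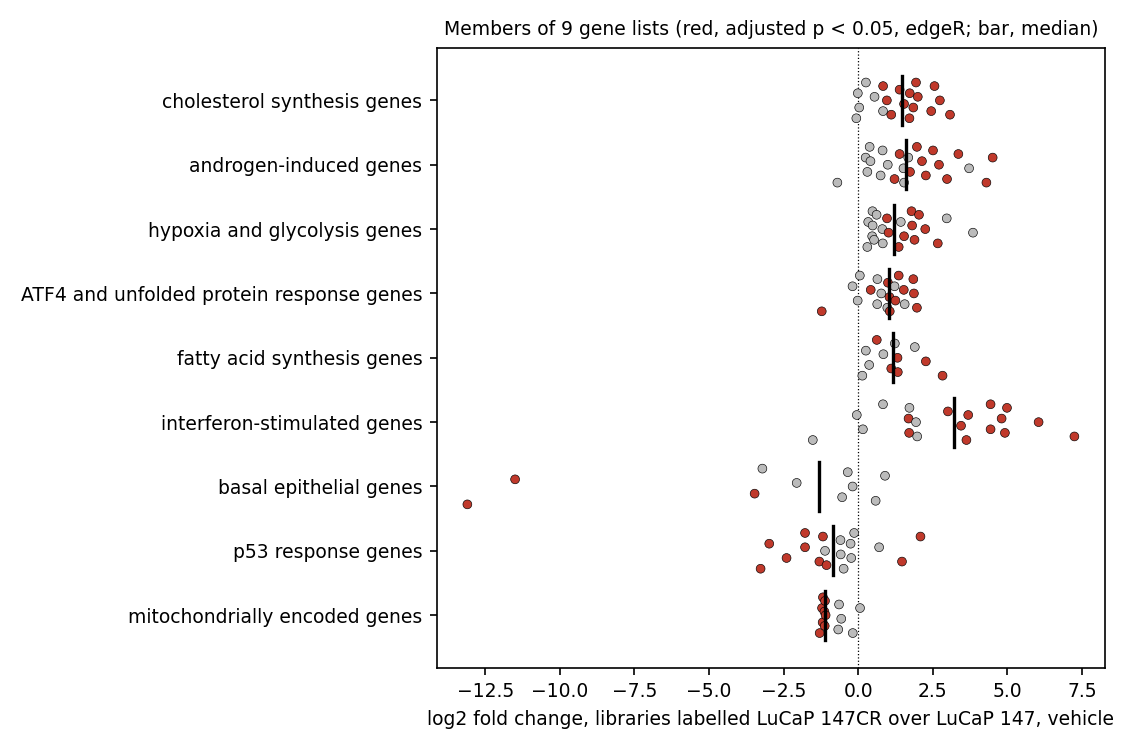
Log2 fold changes of the members of 9 gene lists, LuCaP 147CR over LuCaP 147, vehicle libraries (n = 4 and 4, labels as given). Each point is 1 gene; red points passed an adjusted p of 0.05 in edgeR (Benjamini-Hochberg over all genes tested), grey points did not, and bars are list medians.

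Some treatments were represented by 1 library, compared here by values alone. The LuCaP 147 docetaxel library had lower mitotic and DNA replication transcripts than the 4 vehicle libraries. Of 22 mitotic genes all 22 were lower than the vehicle mean and 21 lay at least 2-fold below the vehicle range (median log2 difference −2.13). Of 22 DNA replication genes all 22 were lower than the mean and 11 at least 2-fold below the range (median −1.29). PLK1, a mitotic kinase, was at 15.5 against 117 CPM (vehicle range 99.5–149), TOP2A, topoisomerase II alpha, at 37.2 against 151 (140–170), and NUSAP1, a spindle protein gene, at 1.80 against 23.7 (19.6–29.5). KRT5 was higher, at 185 against 74.7 CPM (63.9–84.0), and the basal list had a median of 1.00. CYP4F8, which hydroxylates prostaglandins, was at 259 against 14.2 CPM. Of 11930 genes, 276 lay at least 2-fold above the highest vehicle library and 728 at least 2-fold below the lowest, where each vehicle library set against the other 3 gave 29 to 187. The library was the shallowest of the series, at 4087261 counts, and had the highest mitochondrially encoded share, 18.9 percent. All 13 mitochondrially encoded genes were higher than the vehicle mean (median 0.59), while all 24 oxidative phosphorylation genes were lower (−0.98; 95 percent of matched random lists from −0.63 to −0.05). All 28 ribosomal protein genes were lower too (−0.73), within the range of matched random lists (−0.75 to −0.29).

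Batiraxcept plus docetaxel in LuCaP 35 gave 1 library in which CCK, the cholecystokinin gene, stood at 938 CPM against a vehicle mean of 48.8 (1.42–176), and GPC6, a glypican, at 38.4 against 0.788. Of 16 interferon-stimulated genes, 15 were higher than the vehicle mean (median log2 difference 1.69), including IFI6 at 143 CPM against 14.4 (2.15–44.5), and 2 of the list lay at least 2-fold above the vehicle range. The host fibroblast and matrix list had 3 of 4 genes higher (median 2.06). B2M was at 1293 CPM against a vehicle range of 312 to 453, and the antigen presentation list had a median of 1.44. Of 11135 genes, 128 were at least 2-fold above the highest and 251 at least 2-fold below the lowest vehicle library. Each vehicle library against the other 3 gave 251 to 2120 genes outside, a range that holds the 379 of this library. The vehicle libraries held both profiles, which widens their range, so these counts do not show how far the library differed. Against the vehicle libraries in place alone the counts were 280 and 546, the interferon and antigen presentation medians fell to 1.09 and 0.60 and the fibroblast median to −0.73. The immediate early list had a median of −1.28 with 6 members at least 2-fold below the range. The LuCaP 35CR vehicle library, set against the same vehicle libraries, also had a negative median for this list (−0.935).

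In the LuCaP 35CR vehicle library, set against the 4 LuCaP 35 vehicle libraries, interferon-stimulated genes had a median log2 difference of 2.22, with 6 members at least 2-fold above the vehicle range: MX1 was at 25.9 CPM against 2.67 (0.231–5.75) and IFI6 at 168 against 14.6 (2.18–45.2). The host fibroblast and matrix list was higher too (5 of 5 genes, median 2.55). Against the vehicle libraries in place the medians were 1.5 for the interferon list and 0.63 for the fibroblast list. There the immediate early list had a median of −0.935 (13 of 13 genes lower), the NF-kappaB and inflammatory list −1.24 and the mitotic list 0.53. Such shifts were thus not particular to treated libraries. Hypoxia (0.60) and cholesterol synthesis (0.48) lists were higher than the vehicle mean, and the mitochondrially encoded and ribosomal protein (−0.53) lists lower. GPC6 had a log2 difference of 5.82, and CBS, which makes cystathionine, was at 115 against 2.91 CPM, a level that its near-identical copy CBSL makes uncertain. Of 11212 genes, 95 lay at least 2-fold above and 78 at least 2-fold below the vehicle range, 196 and 140 without the libraries standing apart. The 173 outside were fewer than the 251 to 2120 that each LuCaP 35 vehicle library gave against the other 3. The 2 sets of counts are not alike, since 3 libraries have a narrower range than 4. Against 3 vehicle libraries the LuCaP 35CR library gave 183 to 931. The vehicle libraries also held both profiles, which widens their range. The counts therefore do not show whether LuCaP 35CR differed less from LuCaP 35 than its replicates did. The library correlated at a median of 0.964 with the 5 LuCaP 35 libraries in place and of 0.788 with the 3 standing apart.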

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

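All tests weighed in this part were chosen only after the result was seen. Of 76 groups of 4 or 5 values examined, 8 held a library far from the others. Chance gives about 1 in 20 for normally distributed values, which values near 0 are not. Where all others were at 0, as for AXL and CHGA in LuCaP 147 vehicle, any count would be flagged. In those 2 libraries, replicates 3 and 4, 3 counts came to 0.235 and 0.262 CPM before TMM scaling.

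In LuCaP 147, batiraxcept replicate 2 held 32.9 M counts, where the other 3 held 8.60 to 10.5 M. The mitochondrially encoded share was 17.2 percent in LuCaP 35 vehicle replicate 2 and 5.36 to 5.90 percent in the other 3. AXL was at 0.205 CPM in LuCaP 147 vehicle replicate 3 (0 in the others) and at 1.02 CPM in LuCaP 35 vehicle replicate 2 (0 to 0.152 in the others). LuCaP 35 vehicle replicate 4 had 144 CPM of KLK2 (1.5 to 18.5 in the others). CHGA was at 0.322 CPM in LuCaP 147 vehicle replicate 4 (0 in the others). SYP was at 3.96 CPM in LuCaP 147 vehicle replicate 3 (1.43 to 1.85 in the others) and at 6.83 CPM in LuCaP 147CR vehicle replicate 2 (3.47 to 3.72 in the others).

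In 6 libraries the profile went with the other LuCaP number, 3 from each of LuCaP 147CR and LuCaP 35. The tables argue against tumour of both models mixed in 1 library, since genes specific to the labelled model reached at most 0.294 percent of their usual level there, and against an effect of treatment, since 4 vehicle libraries were among the 6. Genes specific to the other model reached 74.3 to 84.75 percent of their level there in the 3 LuCaP 147CR libraries. In the 3 LuCaP 35 libraries they reached 80.5 to 95.4 percent. In expression the 6 thus went with tumour of the other model and not with that of their label. Labels exchanged between the models remain open as a candidate explanation: as many libraries stood apart in one model as in the other, and the lower of their median correlations with the other model was 0.960, above the lowest found within either model's libraries in place. The tables do not show at which step an exchange may have happened, and a biological explanation was not tested.

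The higher interferon-stimulated genes of LuCaP 35 with batiraxcept were weighed on the mean log2 CPM of the list. Blood or marrow cells stay open: PTPRC, the common leukocyte antigen gene, was at 0 CPM in every batiraxcept library of LuCaP 35, but host cells are of the mouse, and removal of mouse reads was not given. The 6 blood or marrow genes above 1 CPM differed by a median of −0.09, with an SD of 1.04 between genes, and do not decide it. Chance assignment stays open with the labels as given (difference 2.61, exact permutation p = 0.171, smallest possible 0.0286). Ranked by unadjusted camera p instead, the real groups gave the smallest of 35 splits (3.7e-19, next 2.9e-17), so the 2 measures differ. The average over 3 models without the 6 libraries gave a difference of 1.5 with an exact permutation p = 0.0324 (0.259 adjusted over 8 such tests). A spread between mice that had no batiraxcept stays open too, though it rests on labels that may be in doubt. Among 6 such libraries with the LuCaP 35 profile the list ranged from 2.03 to 5.77. The 2 batiraxcept libraries were at 6.01 and 6.55. Of the 6, those labelled LuCaP 147CR were at 2.56, 4.53 and 5.77. If labels were exchanged, their treatment labels may be wrong too, so these values cannot decide it. The 2 labelled LuCaP 35 were at 2.03 and 3.24, and the LuCaP 35CR library was at 4.49. The library given both drugs was at 3.53. An interferon response to batiraxcept in LuCaP 35 is a hypothesis that these libraries may be too few to decide.

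The lower ribosomal protein and mitochondrially encoded genes of LuCaP 147 with batiraxcept could be a chance assignment of libraries: 5 of 35 splits of the 8 libraries gave a camera p as small for the ribosomal list and 3 of 35 for the mitochondrial list. Chance stays open for the ribosomal list in the other models too. In LuCaP 147CR another split gave an unadjusted camera p of 7.6e-11, against 1.3e-07 for the real groups. In LuCaP 35 another split gave 3.7e-13, against 3.5e-06. The share of counts taken by mitochondrial genes is argued against for the ribosomal list: that share fell, which left more counts to all other genes (log2 change 0.066 ± 0.026, estimate ± SE), while the ribosomal median was −0.30 (SD between genes 0.13). An effect of batiraxcept on these genes stays open and was not tested otherwise.

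Other splits of the same libraries were counted for each comparison of groups of at least 3. Chance is argued against for LuCaP 147CR against LuCaP 147, where 1 of 35 splits, the real one, called as many genes (4806, highest of the others 1). That is the smallest share that 35 splits can give. The real grouping held 2 libraries standing apart among the LuCaP 147CR vehicle libraries, so the 4806 genes set a mix of 2 profiles against LuCaP 147. For batiraxcept the real count was 0, which every split reaches, so these splits decide nothing about chance: 35 of 35 splits in LuCaP 147 (highest other 5), 100 of 100 drawn in LuCaP 147CR (highest other 0), 35 of 35 in LuCaP 35 (highest other 5352), 60 of 60 for the average (highest other 5258) and 60 of 60 for the interaction (highest other 4293). The 5352 genes came from the split that follows the libraries standing apart, which points to a structure of the samples other than treatment.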

How the results depend on the processing

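The tests without the 6 libraries standing apart and with the profile family as a covariate were chosen only after the result was seen; the others were planned. Of counts of genes, 176 alternatives gave a value within 1.5 times the original and 29 did not; of list tests 731 kept direction and call, 197 lost the call and 12 reversed; of named genes 27166 kept both, 296 gained a call, 212 lost one, 2 reversed and 847, not called originally, changed direction. The estimated correlation ended each of the 44 camera calls, and fry kept 9, all between LuCaP 147CR and LuCaP 147. Without the 6 libraries fry called 5 lists on average over the models.

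The counts of 0 moved as follows. DESeq2 called 32 genes for batiraxcept in LuCaP 147, 545 in LuCaP 147CR, 57 on average, 44 for the interaction and 4 for docetaxel against batiraxcept. limma voom called 3914 in LuCaP 35 and 7541 for the interaction. Without a filter LuCaP 147 gave 130. With the profile family as a covariate the average and the interaction each stayed at 0. Without the 6 libraries the average gave 43, the interaction 44 and docetaxel against batiraxcept 2. Leaving out 1 library gave 0 to 4 in LuCaP 147 (4 without vehicle replicate 3, 1 without vehicle replicate 2 or batiraxcept replicate 2) and 0 to 1 for the interaction (1 without LuCaP 35 batiraxcept replicate 3). The cause was not tested.

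LuCaP 147CR against LuCaP 147 gave 3790 to 5926 genes leaving out 1 library, 6174 with the profile family as a covariate and 3201 in the joint fit, 3190 of them among the 4806; the cause was not tested. RPL30, called there, went to log2 −0.32 without the 6 libraries and −0.43 with the profile covariate.

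A replicate block, with the replicate number as a block, gave 23 genes in LuCaP 147 and 3776 between LuCaP 147CR and LuCaP 147. Correlations between batiraxcept and vehicle libraries of the same number were 0.17, 0.04, 0.03 and −0.09 in LuCaP 147 and −0.69, 0.59 and 0.84 in LuCaP 35. They did not show pairing in LuCaP 147 and were of mixed sign in LuCaP 35, so the unblocked test was kept.

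Counts for groups of 1 library depend on the filter and on the vehicle libraries. At means of 1 and 20 CPM the LuCaP 147 docetaxel library gave 1968 and 567 genes (1004 at 5 CPM; 1051 to 1293 leaving out 1 vehicle library), the LuCaP 35 library with both drugs 770 and 166 (379; 389 to 1461) and the LuCaP 35CR library 368 and 64 (173; 183 to 931). For the last 2, leaving out LuCaP 35 vehicle replicate 2 gave 1461 and 931, vehicle replicate 4 gave 733 and 462, and the libraries standing apart 826 and 336. Lower filters test more genes, and fewer vehicle libraries have a narrower range.

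Lists that reversed in camera for docetaxel against batiraxcept gave, without the 6 libraries, adjusted p = 0.205 (hypoxia), 0.527 (oxidative phosphorylation), 0.937 (ribosomal proteins) and 0.721 (interferon). With the profile covariate oxidative phosphorylation gave 0.436, interferon 0.461 and antigen presentation 0.670. Leaving out 1 library gave 3.1e-06 to 0.0439, 0.0312 to 0.610, 6.7e-06 to 0.940 and 0.0174 to 0.799 in the same order, the highest each time without docetaxel replicate 2 and in the opposite direction, so that 0.0439 was a call for lower hypoxia genes. Docetaxel replicate 2 was the docetaxel library standing apart. Its mean log2 CPM was 7.77 for hypoxia, 10.4 for ribosomal proteins and 4.53 for interferon. The other docetaxel library was at 5.25, 9.42 and 2.08, and the batiraxcept means were 5.84, 9.44 and 2.27. The higher values of these 3 lists with docetaxel thus came from the library standing apart. Oxidative phosphorylation on average reversed without the 6 libraries (0.783, range over its alternatives 1.1e-05 to 0.887). Other causes of these reversals were not tested.

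Depth limits the genes near 1 CPM, such as AXL, whose 67 counts allow no comparison between groups.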

Other observations

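The tests without the 6 libraries standing apart were chosen only after the result was seen.

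Among lists that the comparisons above did not describe, homologous recombination and Fanconi genes were all negative with batiraxcept in LuCaP 147CR without the 6 libraries (16 of 16, median log2 fold change −0.39), with FANCD2, a central Fanconi gene, at 41.0 ± 19.2 against 59.8 ± 1.25 CPM (n = 5 and 2). In the same setting of LuCaP 35 the microtubule list had a median of 0.71, the mitotic list 0.50 and the NF-kappaB and inflammatory list −1.64 (n = 2 and 2). No list was called with an estimated correlation in either model in this setting (smallest adjusted p = 0.916 and 0.684 with an estimated correlation), nor by fry (0.583 and 0.114). The LuCaP 35CR vehicle library, set against the same 2 LuCaP 35 vehicle libraries, had medians of 0.40, 0.53 and −1.24 for the microtubule, mitotic and NF-kappaB lists. Between LuCaP 147CR and LuCaP 147 vehicle tumours (n = 4 and 4) the ubiquitin hydrolase gene UCHL1 had a log2 fold change of −7.83 (−8.92 without the 6 libraries), NR3C1, the glucocorticoid receptor gene, 8.02 (5.71), and HLA-B 5.74 (1.55). Of host-type markers, VWF of endothelium had a log2 fold change of −2.42 there (−1.84 without the 6 libraries) and COL1A1 of matrix −1.22.

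No pair of libraries within a group looked like a repeat of the same sample: over genes with at least 20 counts the lowest chi-square per degree of freedom between replicates was 10.5. The proliferation gene MKI67 was expressed in every library (median 182 CPM, 47.5 to 350).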
